A study of Mus musculus with 15 samples.

How the data were processed

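Total RNA from 15 mouse hearts was hybridised to short oligonucleotide expression arrays, 1 array per heart. Groups were taken from the sample titles, and replicate numbers only name the arrays. The deposited data are 2 value tables of 22690 probe sets, 1 for the 9 wild-type and 1 for the 6 knockout arrays, so genotype cannot be separated from table. The tables also belong to different array models with the same probe sets, so genotype cannot be separated from array model either. The processing software is not given in the sources used here.

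The wild-type values are a standardised score, as tested on the deposited table itself: undoing a linear step per array left every probe set with a mean of 0 and an SD of 1.0 over the 9 arrays, and each array as deposited has an SD of 1.0. Differences are therefore in standardised units, in which a gene of small and a gene of large change look alike, and cannot be turned into folds. The knockout values are a score that behaves as a log difference centred per probe set, from -7.78 to 8.18, with the log base not given; 54.2% of probe sets have 1 array at exactly 0 in the deposited table. CLP replicate 1 and sham replicate 1 hold no such value, against 2992 to 3122 in each of the other 4 columns, for a reason that is not given. In sham replicate 1 the value 0.018 recurs, as in Lcn2, S100a8, Ppara and Pdk4. Its mean is 0.0037 against -0.0144 in those 4 columns, as a constant shift of that column would give. No intensities were used, so neither signal over background nor a filter on dim probe sets was available.

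The 64 control probe sets were left out, and 22626 remained. The platform annotation, equal for both array models, paired 20380 with 1 gene, 691 with several and 1555 with none; only the first were used, giving 12393 genes. The plan fixed before the data were examined called for the probe set of highest level per gene, which standardised values do not allow. The mean of all probe sets of a gene, an alternative fixed before the data were examined, was used in its place. That choice was made after the counts by gene mean and by probe set had both been seen: testing every probe set gives the larger count, 582 probe sets in 486 genes against 89 genes by the mean, and had first been preferred. The mean was kept because the plan fixed genes as the unit, and both counts are given. Cpt1b, named in the plan, lies only on a probe set with several genes and is not reported.

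Groups were compared with lmFit of limma 3.58.1 in R 4.3.3, all 9 wild-type arrays in 1 fit, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The plan named eBayes. On rows scaled to equal SD, moderation pulls the residual spread towards a common value, so unmoderated statistics on 6 residual degrees of freedom were used for wild type. This weakness was noted from the form of the values before any count was made. The choice was settled, and the simulation below run, after both counts (0 and 89) had been seen. On simulated data of the same form (12393 genes), these recovered 50%, 84%, 100% and 100% of changes of 4, 6, 8 and 10 residual SDs with 7 false calls, and eBayes recovered 0% of each. On the real wild-type data eBayes calls 0 genes in every comparison, so each wild-type count depends on this departure. Knockout arrays were tested with eBayes. The knockout CLP replicate 1 was left out, decided before any knockout count was seen. The reason was that it follows the other CLP columns (R squared 0.746 on the other 5 columns). Simulations without any change used a column that is a mean of the 3, which the deposited column resembles. This raised the share of genes at an unadjusted p under 0.05 from 5.25% to 9.97%, with 0 genes past the adjusted threshold in either case. With 5 arrays, simulated changes of 2, 3, 4 and 6 log units were recovered in 10%, 38%, 56% and 90% of genes, with 0 false calls. In both simulations probe sets of a gene had independent noise, which real ones need not have.

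Gene lists (28 pathway and 16 cell type lists with at least 5 measured members, written before the data were examined) were tested with camera at a preset correlation of 0.01, adjusted over the 44 lists; an estimated correlation and fry were run beside it. With the estimated correlation no list passed in any comparison. Fry, which tests a list without setting it against other genes, passed 13 lists for wild-type CLP (camera 18), 4 for Max Dep against sham (camera 14), 11 for Min Dep against sham (camera 21), 0 for Max Dep against Min Dep (camera 9) and 1 for knockout CLP (camera 21). List tests of each septic group against sham were not planned. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of 1 list. They do not account for the other lists or genes tested, and were not in the plan either. Camera compares a list with the other genes, and it also passed many lists on arbitrary groupings of these arrays, so its p-values are too small here. Named genes were, per comparison, the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap (the 4 smallest p in each direction where none passed), up to 4 members of smallest p per list described, and a set of 15 genes chosen in advance. Alternatives were normalisation, array weights, leaving out each array, groups in the fit, unit of testing and threshold; those chosen after seeing the data were unmoderated statistics for wild type (with the planned eBayes run beside them), robust eBayes, undoing the array step, the control probe set covariate, all 6 knockout columns, unmoderated knockout statistics and cameraPR.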

Results

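Whole hearts of mice were profiled on oligonucleotide expression arrays 48 h after surgery, in a study of the myocardial depression that accompanies sepsis. Polymicrobial sepsis was produced by caecal ligation and perforation (CLP), in which the caecum is tied off and punctured so that gut bacteria reach the abdominal cavity, and control mice had a sham operation. The 15 arrays formed 5 groups of 3. The 9 wild-type arrays comprised sham hearts and septic hearts that the labels divide into a Min Dep and a Max Dep group. The 6 knockout arrays comprised sham and CLP hearts of mice lacking Nos2, the inducible nitric oxide synthase. The labels give each array its own code, and the number of arrays limits the precision of every value. What the codes stand for is not given, so an order of handling or a batch tied to surgery could not be assessed. Wild-type values were deposited in standardised units and carry no expression level or fold change. Knockout values are log differences whose base is not given, and they come from another array model, so the genotypes were never compared in level.

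Nos2, the targeted gene, was measured by 1 probe set. In wild-type hearts its values were 1.40, -0.30 and -0.91 after sham surgery, -0.02, 1.78 and 0.22 in the Min Dep group and -0.91, -0.31 and -0.98 in the Max Dep group. In the knockout table they were 0.12, -0.72 and 1.06 after sham surgery and -0.35, -1.44 and 0.57 after CLP. Each table was centred on its own arrays and the position of the probe set relative to the deletion is not given, so these values do not check the genotype labels. The CLP difference in wild type was -0.10 ± 0.65 standardised units (SE; adjusted p = 0.954, limma).

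The first comparison asked which genes differed between septic and sham wild-type hearts. After CLP, 42 genes rose and 47 fell, 89 of 12393 in all (limma, unmoderated statistics, Benjamini-Hochberg). The largest rises included Fcer1g and Tyrobp, signalling adaptors of myeloid cells, at 2.03 ± 0.22 and 2.01 ± 0.19 standardised units (SE). Myh7, the slow beta myosin heavy chain, rose by 2.03 ± 0.18, and Calr, a calcium-binding chaperone of the endoplasmic reticulum, by 2.02 ± 0.24. The other leading rises were Oard1 (2.02), Ankrd33b (2.02), the homeobox gene Meis1 (2.01) and the nucleotide receptor gene P2ry6 (2.01). The largest falls were in Synpo2 (-2.14 ± 0.18), Opa1 (-2.14 ± 0.19), which encodes a fusion protein of the inner mitochondrial membrane, and Epas1 (-2.14 ± 0.25), which encodes a hypoxia-inducible factor. Syap1 (-2.12), Prepl (-2.10), the adhesion molecule gene Bcam (-2.10), Phkg1 (-2.09), a catalytic subunit of phosphorylase kinase, and Qpct (-2.09) followed. Adjusted p-values of these 16 genes lay between 0.0199 and 0.0498. As an example of the spread, Prepl was at 1.39 ± 0.26 in sham hearts (SD, n = 3) and -0.71 ± 0.19 after CLP (SD, n = 6), and Tyrobp went from -1.32 ± 0.32 to 0.69 ± 0.47.

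**Figure D1:**
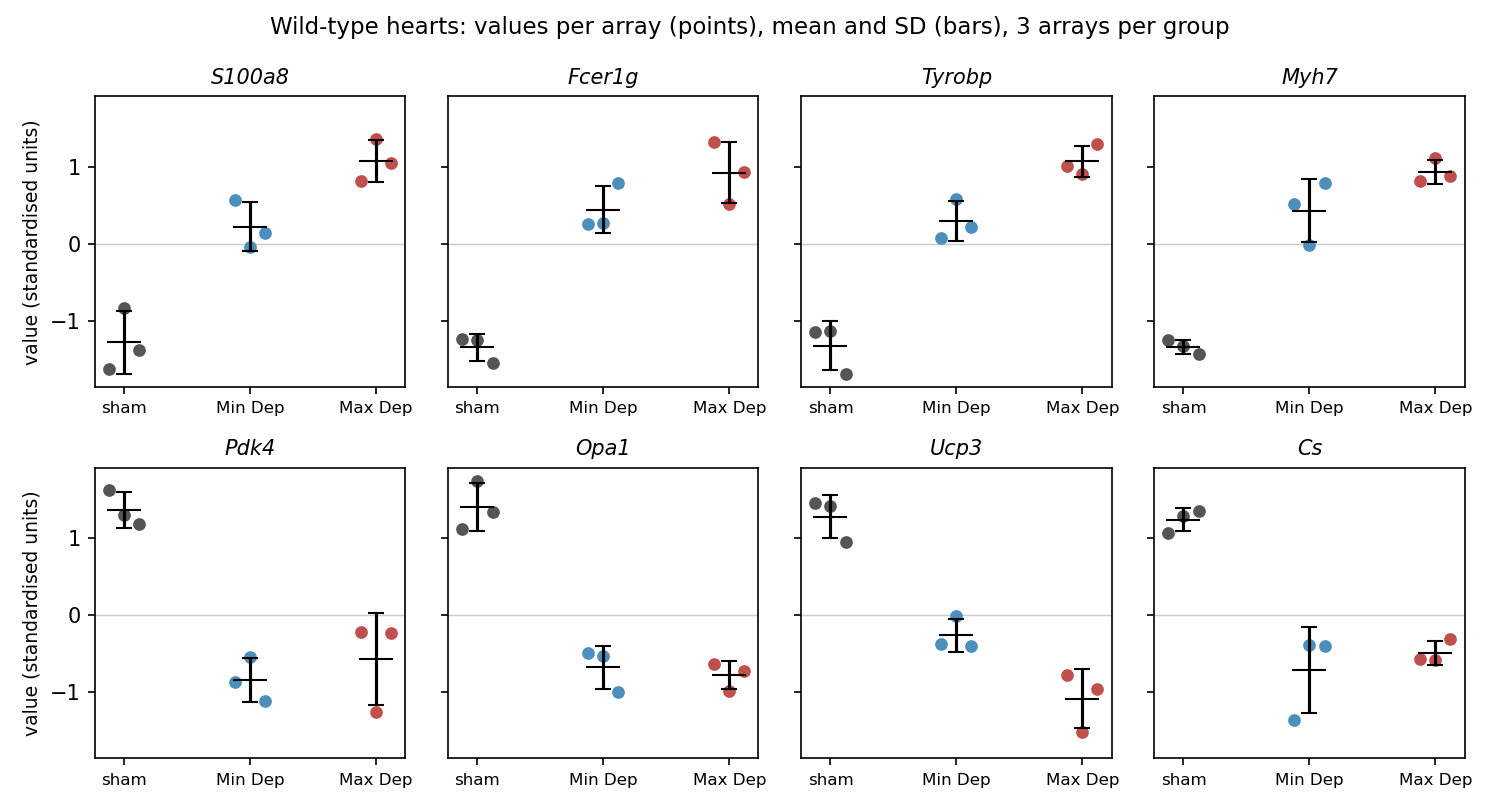
Values of 8 genes in the 9 wild-type arrays, in standardised units on the vertical axis, with sham, Min Dep and Max Dep groups on the horizontal axis; points are arrays and bars the mean and SD of 3 arrays. The 8 genes were picked for display after their values were seen, and the 3 sham arrays lie apart from the 6 CLP arrays, as in Tyrobp (mean -1.32 in sham hearts, 0.69 after CLP) and Opa1 (1.41 and -0.73).

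Of 18 measured macrophage and monocyte genes, 2 rose (Tyrobp and Fcer1g) and none fell, or 10 rose when adjusted over the list alone. Adgre1 (1.98 ± 0.29) and C1qa (1.94 ± 0.30) had an adjusted p of 0.0543. The list stood above other genes (camera, adjusted p = 8.84e-08), with adjusted p = 0.241 with an estimated correlation. Of 13 neutrophil genes, S100a8 (1.93 ± 0.24) and S100a9 (1.92 ± 0.26), subunits of calprotectin, rose and the other 11 did not pass. In this list 3 rose when adjusted over the list alone (camera adjusted p = 0.00188; adjusted p = 0.328 with an estimated correlation). Mpo differed by 1.60 ± 0.31 and Lcn2, an iron-sequestering acute phase protein, by 1.64 ± 0.53 (adjusted p = 0.186). The acute phase list as a whole did not pass (camera adjusted p = 0.05002), and 0 of its 27 members rose. It passed without sham replicate 2 (camera adjusted p = 0.0122) or without Max Dep replicate 2 or 3 (0.0468 and 0.0317). By group it lay higher in Max Dep (median 0.84, camera adjusted p = 0.00832) and did not pass in Min Dep hearts (median 0.44, camera adjusted p = 0.402). Between Max Dep and Min Dep hearts the list did not pass (camera adjusted p = 0.0605). For Max Dep against sham, adjusted p = 0.421 with an estimated correlation. The Max Dep result did not pass without sham replicate 1 (0.0665) or Max Dep replicate 1 (0.0522). T and natural killer cell genes (median -0.25, camera adjusted p = 0.507) and B cell genes (median -0.24, camera adjusted p = 0.484) did not pass either.

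Of 26 genes of fatty acid uptake and oxidation, Ucp3 (-1.96 ± 0.21), Etfdh (-2.07 ± 0.28) and Pdk4 (-2.08 ± 0.29) fell and none rose. Adjusted over the list alone, 12 fell and 1 rose (camera adjusted p = 4.13e-06; adjusted p = 0.348 with an estimated correlation). Pdk4 encodes a kinase that inhibits pyruvate dehydrogenase, and Etfdh passes electrons from fatty acid oxidation to ubiquinone. Of 17 genes of the tricarboxylic acid cycle, Cs, citrate synthase, fell (-1.84 ± 0.24) and 7 fell and 2 rose when adjusted over the list alone (camera adjusted p = 4.44e-05; adjusted p = 0.241 with an estimated correlation). Glycolytic genes (0 of 24 passing; camera adjusted p = 0.0153) and respiratory chain subunits (0 of 67; camera adjusted p = 0.0437) lay lower as lists, with adjusted p = 0.241 and 0.571 with an estimated correlation. Against sham, both lists passed in Min Dep hearts (respiratory chain median -0.91, camera adjusted p = 0.000251; glycolysis median -1.08, camera adjusted p = 0.00197) and neither in Max Dep hearts (medians -0.11 and -0.57, camera adjusted p = 0.855 and 0.189). With an estimated correlation the Min Dep values were 0.347 and 0.297. Between Max Dep and Min Dep hearts the glycolysis list did not pass (camera adjusted p = 0.0755). The respiratory chain list did (camera adjusted p = 9.48e-05, or 0.525 with an estimated correlation). For both groups together, the respiratory chain list did not pass without sham replicate 2 or 3 (0.134 and 0.0705), Min Dep replicate 1 (0.164) or Max Dep replicate 2 or 3 (0.0509 and 0.17). Sod2, the mitochondrial superoxide dismutase, fell (-1.95 ± 0.22), while its antioxidant list did not pass (camera adjusted p = 0.857).

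All 12 fibroblast genes had a negative difference and 0 passed, with 3 falling when adjusted over the list alone (median -1.53, camera adjusted p = 3.23e-06), with Mfap5 at -1.93 ± 0.34 and Lum at -1.81 ± 0.44. Extracellular matrix genes had a median of -1.54 (0 of 31 passing, 11 falling and 1 rising when adjusted over the list alone, camera adjusted p = 4.75e-07), and Eln differed by -1.98 ± 0.33 and Timp3 by -1.95 ± 0.34. Smooth muscle and pericyte genes (median -1.42) and adipocyte genes (median -1.58) were also lower as lists (camera adjusted p = 8.16e-05 and 2.35e-05), with 0 members passing. Adjusted over the list alone, 5 of 11 smooth muscle and pericyte genes fell and 1 rose, and 1 of 9 adipocyte genes fell. The mean of the adipocyte genes was 1.64 and 1.51 in sham replicates 2 and 3 but -0.18 in sham replicate 1, within the range of the CLP arrays (-1.02 to 0.03). With an estimated correlation each of these 4 lists had an adjusted p of 0.328. Among 28 cytosolic ribosomal protein genes, Rpl6 (1.91 ± 0.17), Rpl35 (1.47 ± 0.16), Rps28 (1.74 ± 0.22) and Rpl4 (1.91 ± 0.26) rose. Of the 28, 22 rose when adjusted over the list alone (camera adjusted p = 4.12e-09; adjusted p = 0.241 with an estimated correlation). Of 22 endoplasmic reticulum stress genes, Xbp1 (1.68 ± 0.15) and Calr rose, and 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00209; adjusted p = 0.328 with an estimated correlation).

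Among sarcomere genes, Myh7 rose and Nebl fell (-2.06 ± 0.28), and the list did not pass (23 members, camera adjusted p = 0.153). Calcium handling and beta-adrenergic genes were lower as a list (0 of 23 passing, 9 falling and 1 rising when adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.328 with an estimated correlation), with Ryr2, the calcium release channel, at -1.65 ± 0.31 (adjusted p = 0.0706). The list did not pass without sham replicate 1 (camera adjusted p = 0.0563) or Min Dep replicate 1 (0.0552). The remaining genes chosen in advance did not pass: Atp2a2 (-0.41 ± 0.34), Pln (-0.19 ± 0.33), Myh6 (-0.45 ± 0.46), Nppa (0.42 ± 0.86), Nppb (-1.11 ± 0.73), Ppara (-0.52 ± 0.72) and Ppargc1a (-1.28 ± 0.50). The 2 probe sets of Myh6 differed in sign (-1.91 and 1.01), as did those of Atp2a2 and of Pln. With every probe set tested, 1 probe set of Ryr2 (-2.11, adjusted p = 0.0257) and 1 of Ppargc1a (-2.06, adjusted p = 0.034) passed.

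The count of 89 rested on the full set of arrays. It was 0, 0 and 2 without sham replicate 1, 2 or 3, 0, 186 and 1 without Min Dep replicate 1, 2 or 3, and 0, 4 and 12 without Max Dep replicate 1, 2 or 3. With eBayes moderation 0 genes passed, and with every probe set tested 582 probe sets passed. In all 18 lists passed by camera, 13 of them also by fry, as many as the highest of the other groupings among 100 of the arrays. The difference between 5' and 3' control probe sets was averaged over Gapdh and Actb, in standardised units. It was 0.90 ± 0.75 in sham, -0.19 ± 0.33 in Min Dep and -0.71 ± 1.19 in Max Dep hearts (SD, n = 3 each). On values standardised per probe set it is a rough guide to RNA integrity and not a ratio of the ends. The 2 controls could differ, as in Max Dep replicate 3 (Gapdh -3.12, Actb -0.57). With this difference as a covariate 1 gene passed. Sham replicate 1 had female-like values of sex-linked genes, with Eif2s3y at -2.48 against -0.68 or above in the other 8 arrays.

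Max Dep hearts against sham gave 36 genes that rose and 20 that fell. Tyrobp (2.40 ± 0.21), P2ry6 (2.44 ± 0.24) and S100a8 (2.36 ± 0.28) were among the rises, with Paf1 (2.49), the ribosomal protein gene Rpl6 (2.45), Krtcap2 (2.43), Pfdn6 (2.42), Mlec (2.40) and Ybx3 (2.39). Myh7 rose by 2.28 ± 0.21. Falls were led by Pafah1b3 (-2.38 ± 0.29), the mitochondrial carrier gene Ucp3 (-2.37 ± 0.25), Ppp1r3c (-2.29 ± 0.23), a glycogen-targeting phosphatase subunit, Kremen1 (-2.24), Hhatl (-2.21), Synpo2 (-2.20), Opa1 (-2.19) and Ate1 (-2.19). Pdk4 (-1.94 ± 0.33, adjusted p = 0.0823) and S100a9 (2.31 ± 0.30, adjusted p = 0.0527) did not pass. The count of 56 was 7 when only these 6 arrays were fitted, 0 under eBayes moderation or with the 5' minus 3' control difference as a covariate, and 0 without sham replicate 1 or 2, Min Dep replicate 1, or Max Dep replicate 1 or 3. It was 6 without sham replicate 3, 26 and 10 without Min Dep replicates 2 and 3, and 3 without Max Dep replicate 2.

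Min Dep hearts against sham gave 2 genes that rose, Fign (2.17 ± 0.17) and the DNA repair polymerase gene Polb (1.62 ± 0.14), and 5 that fell. The falls were Mcts1 (-2.51 ± 0.22), Tmem100 (-2.49 ± 0.19), Prepl (-2.20 ± 0.17), Phkg1 (-2.13 ± 0.13) and the laminin chain gene Lamb1 (-2.04 ± 0.17). Pdk4 (-2.22 ± 0.33, adjusted p = 0.0724), Ryr2 (-2.07 ± 0.35, adjusted p = 0.0788), Myh7 (1.78 ± 0.21, adjusted p = 0.0626) and S100a8 (1.51 ± 0.28, adjusted p = 0.0871) did not pass. Whether the 2 septic groups differ from sham to a different extent is answered by their direct comparison. The count of 7 was 1 when only these 6 arrays were fitted, 0 under eBayes moderation, 2 with the 5' minus 3' control difference as a covariate. It was 0 without sham replicate 1 or 2 or Min Dep replicate 1 or 3, 3 without sham replicate 3, 68 without Min Dep replicate 2, and 2 and 1 without Max Dep replicates 1 and 2.

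The direct comparison of Max Dep with Min Dep hearts asked what differed between the septic groups, and what quantity their labels rank is not given. Here 0 of 12393 genes passed (limma; 1216 at an unadjusted p under 0.05, and 0 with eBayes moderation or with every probe set tested). Values with the smallest p were Ifitm2 (2.44 ± 0.21, adjusted p = 0.0852), Ttc13 (1.49 ± 0.13), Fkbp1a (1.46 ± 0.15) and Timm44 (2.07 ± 0.24) higher, and Btrc (-1.42 ± 0.11), Rasgrp1 (-1.35 ± 0.11), Sprr1b (-2.18 ± 0.24) and Afp (-1.42 ± 0.16) lower in Max Dep hearts. S100a8 differed by 0.85 ± 0.28 (adjusted p = 0.443), Tyrobp by 0.78 ± 0.21, Ryr2 by 0.83 ± 0.35, Pln by -1.0 ± 0.38 and Nos2 by -1.39 ± 0.75. As lists, 8 lay higher and 1 lower in Max Dep hearts by camera, and 0 passed by fry. Genes responsive to glucocorticoids had a median of 1.08 (camera adjusted p = 9.48e-05; adjusted p = 0.226 with an estimated correlation), with Sgk1 at 2.24 ± 0.43 and Tsc22d3 at 1.65 ± 0.42, and 1 of 16 rose when adjusted over the list alone. Against sham this list lay lower in Min Dep hearts (median -1.10, camera adjusted p = 0.0102, or 0.0671 without Min Dep replicate 2 and 0.297 with an estimated correlation) and did not pass in Max Dep hearts (median 0.13, camera adjusted p = 0.494). Proteasome (28 of 31 members higher), respiratory chain (50 of 67), ribosomal (24 of 28), heat shock (13 of 14) and macrophage genes (18 of 18) were higher on balance, and B cell genes lower (8 of 9), with camera adjusted p between 9.48e-05 and 0.00919. Adjusted p for each of these 6 was 0.525 with an estimated correlation. By the mean of their members, the groups overlapped for proteasome and respiratory chain genes. The proteasome mean was 0.40 in Min Dep replicate 3 against 0.06 in Max Dep replicate 2. The respiratory chain mean was -0.10 in Min Dep replicate 3 against -0.15 in Max Dep replicate 3. B cell genes did not pass without Min Dep replicate 2 (camera adjusted p = 0.114), in which their mean was 1.29 against -0.08 and 0.10 in the other Min Dep arrays. Macrophage genes did not pass without Min Dep replicate 3 (0.121) or Max Dep replicate 3 (0.0645), nor heat shock genes without Min Dep replicate 3 (0.111). Extracellular matrix (median 0.49, camera adjusted p = 0.027) and mesothelium genes (median 0.76, camera adjusted p = 0.0466) were also higher, with adjusted p = 0.698 and 0.525 with an estimated correlation. Extracellular matrix genes did not pass without Min Dep replicate 3 (0.598) or Max Dep replicate 3 (0.152), nor mesothelium genes without Min Dep replicate 2 or 3 (0.0922 and 0.153) or Max Dep replicate 2 (0.249). Adjusted over the list alone, 3 ribosomal and 2 heat shock genes rose and 3 B cell genes fell, while over all genes 0 members of any list passed. Another of the 10 splits of the 6 septic arrays gave 10 lists, and 16 and 15 lists passed without Min Dep replicate 1 and Max Dep replicate 1. Without Max Dep replicate 1 the gene count was 1, and it was 2 with the array standardisation undone.

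CLP was then compared with sham surgery in Nos2 knockout hearts, using 2 CLP and 3 sham arrays. The remaining CLP column was left out because it lay between the other 2 in 76.0% of probe sets, against 27.2% to 29.1% for sham columns, and its SD was 0.68 against 0.98 to 1.09. No gene of 12393 passed (limma with eBayes; 1476 at an unadjusted p under 0.05, 722 higher and 754 lower; 0 without moderation, with robust eBayes or with every probe set tested), and 295 passed when all 6 columns were fitted. Values with the smallest p were higher for Lst1 (4.38 ± 0.42 log units), Lcp1 (3.92 ± 0.43), S100a8 (4.40 ± 0.50) and the complement gene C1qb (4.24 ± 0.48), and lower for Vmn1r11 (-5.21 ± 0.47), Csnk1e (-4.10 ± 0.40), Thbs2 (-4.02 ± 0.40) and the aquaglyceroporin gene Aqp7 (-5.09 ± 0.56), each at an adjusted p of 0.0820. Without passing, Lcn2 differed by 4.53 ± 0.64, S100a9 by 4.58 ± 0.60, Ppara by 5.28 ± 1.36, Myh7 by 3.60 ± 1.01, Myh6 by -2.66 ± 0.72, Nppb by 3.30 ± 1.44 and Pdk4 by -4.97 ± 1.75. Pdk4 was at -6.92 in CLP replicate 3 and -0.58 in CLP replicate 2, against 0.02, 2.09 and 1.57 in sham arrays. Atp2a2 (1.24 ± 0.51), Ppargc1a (0.87 ± 0.47), Ryr2 (0.89 ± 0.77), Pln (0.14 ± 0.85), Nppa (0.08 ± 2.31) and Nos2 (-0.59 ± 0.79) did not pass either.

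As lists, 12 lay higher and 9 lower in septic knockout hearts, none with a member past the threshold over all genes. Macrophage genes had a median of 2.31 log units (12 of 18 rose when adjusted over the list alone; camera adjusted p = 2.81e-13). All 22 endoplasmic reticulum stress genes were higher (median 1.94, 12 rising over the list alone; camera adjusted p = 1.51e-12). In addition 24 of 27 acute phase genes were higher (median 1.69, 11 rising over the list alone; camera adjusted p = 3.57e-09), with Saa3 at 4.56 ± 0.71. All 12 endothelial genes were lower (median -3.21, 9 falling over the list alone; camera adjusted p = 1.25e-10), with Ramp2 at -4.83 ± 0.62 and Tie1 at -3.60 ± 0.55. Antigen presentation genes had a median of -1.06 (5 of 16 falling over the list alone; camera adjusted p = 6.78e-06), with the class II genes Cd74 at -4.36 ± 0.54 and H2-Aa at -5.01 ± 0.64. Fibroblast (median -1.45), smooth muscle and pericyte (median -2.42) and fatty acid oxidation genes (median -0.73) were also lower (camera adjusted p = 8.29e-05, 5.55e-05 and 0.000653). The mean of the fatty acid oxidation genes did not separate the groups. It was -1.10 and -0.37 in the CLP arrays, with sham replicate 1 between them at -0.69, and 0.52 and 1.07 in sham replicates 2 and 3. With an estimated correlation no list passed, and by fry only the antigen presentation list did (adjusted p = 0.0286). Adjusted p = 0.418 with an estimated correlation held for the macrophage, endothelial, antigen presentation and smooth muscle lists, 0.454 for endoplasmic reticulum stress and acute phase genes, 0.530 for fibroblast genes and 0.676 for fatty acid oxidation genes. Another of the 10 splits of the 5 arrays gave 20 lists, against 21 here. The 5' minus 3' control difference was -2.06 and -0.78 in the 2 CLP arrays and -0.26 ± 1.53 in sham hearts (SD, n = 3). Sham replicate 2 had male-like values, with Eif2s3y at 5.76 against 0.10 or below in the other 5 columns and a probe set of Xist at -6.91. In the CLP column left out, that probe set was also low (-3.63), while Eif2s3y was not raised (-0.06). Relative to the array that stood apart in each table, the other wild-type arrays were male-like and the other knockout arrays in the fit female-like. Sex, which the labels do not give, therefore nearly coincided with genotype.

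**Figure D2:**
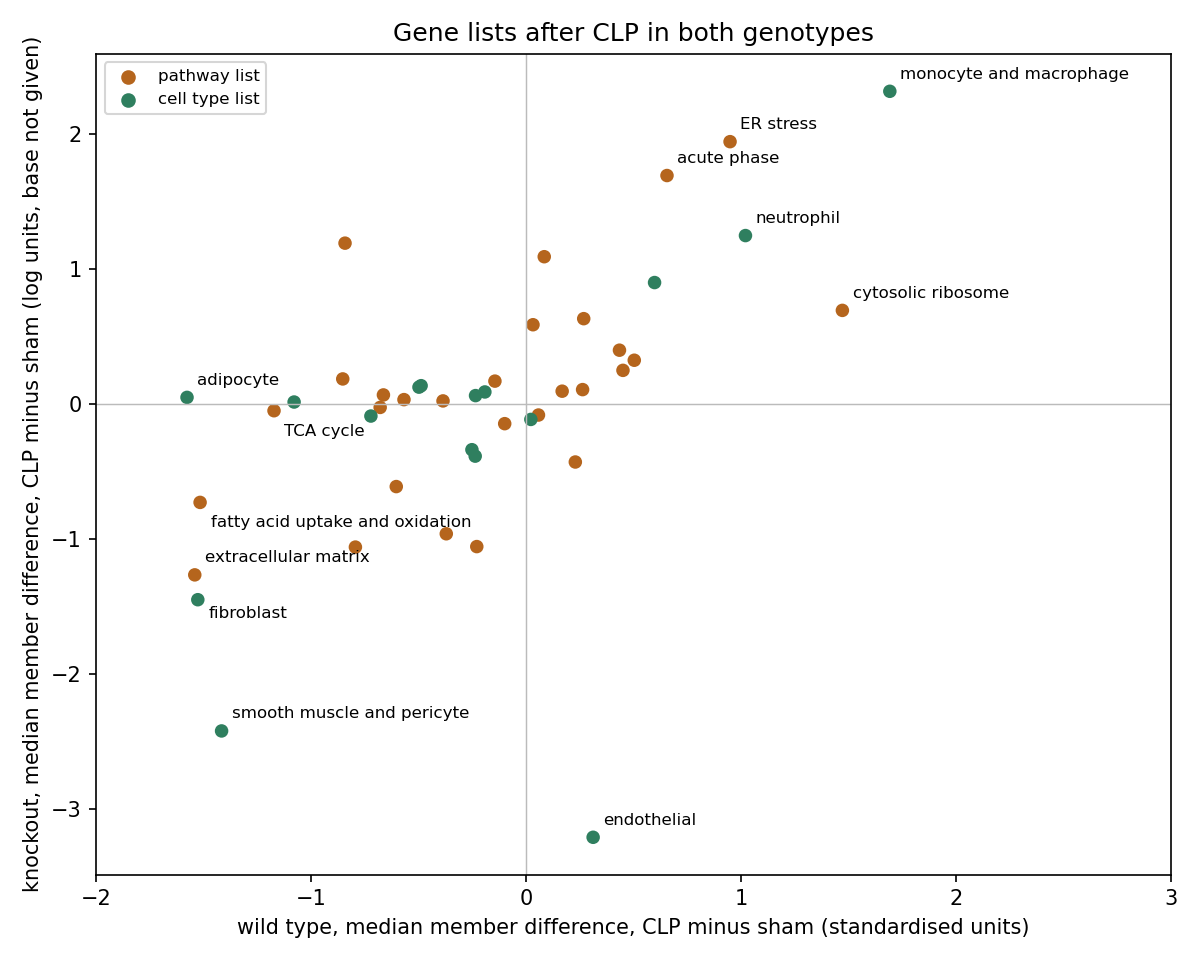
Median CLP minus sham difference of the members of each of 44 gene lists, in wild type (horizontal axis, standardised units) and knockout (vertical axis, log units of unstated base); each point is a list, coloured by pathway or cell type. Macrophage genes lie highest in both (1.69 and 2.31), fibroblast genes are below 0 in both (-1.53 and -1.45), and endothelial genes lie at 0.31 in wild type and -3.21 in knockout.

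Across genes, the CLP differences of the genotypes were related with Spearman's rho = 0.172 and Pearson's r = 0.195, and genes are not independent replicates. Wild-type differences are standardised per probe set and knockout differences are not. Both coefficients are affected by this, so their size does not measure how alike the changes were. Other assignments of the 5 knockout arrays gave a rho between -0.208 and 0.159. Of the 42 genes that rose in wild type, 35 had a positive difference in knockout hearts, and of the 47 that fell, 31 had a negative one, where 55.1% of all genes had the same sign in both. A test of whether the CLP effect differed between genotypes was not run, because 1 table holds standardised units and the other log units. Sex-linked genes also nearly divided the genotypes, so a difference between them cannot be assigned to Nos2 alone.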

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

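All tests in this part were chosen after the results were seen, except those of the control probe sets and of the sex of 1 sham heart, whose bounds were set before their values were seen. Genes singled out here had CLP arrays on 1 side of all sham arrays in wild type and on the other side in knockout. Kdr was higher after CLP in every wild-type array than in sham arrays (1.60 ± 0.39 standardised units) and lower in the knockout arrays (-3.50 ± 0.74 log units). Prkar1a (-1.44 ± 0.47 and 1.37 ± 0.54) and Thbs1 (-1.60 ± 0.40 and 1.09 ± 0.45) were lower in wild type and higher in knockout, and the difference between genotypes was not tested for these 3 genes. They came from 308 named genes, many named for a small p in these data. None of the 3 passed the threshold in either genotype. Of all 12393 genes, 129 (1.04%) met the rule, so 3 of 308 is no excess over other genes. Random placing of the arrays would give 0.238%, a share that does not apply to genes picked in this way.

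The knockout CLP column left out of the comparisons entered only the fits of all 6 columns, and held values above every knockout sham array for S100a8 (2.75 against at most 0.08), S100a9 (2.87 against 0.24) and Lcn2 (2.63 against 0.24). That column may have been computed from the other CLP columns with further input. In 64 control probe sets, which took no part in any knockout fit, it lay between the other 2 in 85.9% (exact 95% binomial interval 75% to 93.4%), against 31.2% to 53.1% for the sham columns. Control probe sets share transcripts and are not independent, which makes the interval too narrow. The tables argue against a plain mean of the other 2. In 247 of 22626 probe sets the column lay outside the other 2 by over 1 log unit, each time below both, as in Xist (-3.63 against 0.05 and 0), which a mean of the other 2 forbids. A mean of all 3 CLP arrays would need values of its own array from -12.83 to 0.61, outside the range of the table in 144 probe sets, whereas the highest values of the other 5 columns were 6.9 to 8.18. That range does not bound an array on another scale, so a mean of all 3 is not excluded. What further input would be needed stays open, and no biological explanation was tested.

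With unmoderated statistics, the 89 genes that passed between septic and sham wild-type hearts exceeded the highest of the other groupings, which gave 2 genes. Only 1 of 100 groupings was as large, which argues against chance assignment for the count under that test. The test was settled after its count and the 0 of eBayes had been seen, and the share does not account for that choice. The tables argue against the sex of the sham heart with female-like values as the whole source of the difference between septic and sham hearts. Without it and over all genes, 1836 had an unadjusted p under 0.05, against at most 1149 in other splits of the 8 arrays into 2 and 6, so 1 of 28 splits was as large. The 89 genes had a median difference of 1.93 before and 1.90 after, which their selection largely fixes. Their median SE went from 0.22 to 0.25 with 1 sham array and 1 residual degree of freedom fewer, and 0 of them passed the threshold. RNA degradation stays open. With the 5' minus 3' control difference as a covariate the genes had 100.6% of their median difference (1.93 before and 1.95 after), while the median SE went from 0.22 to 0.29 and 1 gene stayed past the threshold.

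For Max Dep against sham (56 genes, highest other split 0), Min Dep against sham (7, highest other 0) and Max Dep against Min Dep (0, highest other 1), 10 splits are too few for a share under 0.05; as many genes came from 1, 1 and 10 of them.

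As lists, macrophage and neutrophil markers were higher after CLP in both genotypes by camera with the preset correlation. With an estimated correlation neither passed (adjusted p = 0.241 and 0.328 in wild type, 0.418 for both in knockout). Over all genes 2 of 18 and 2 of 13 members rose in wild type and 0 in knockout. A lower share of cardiomyocytes alone would raise the markers of other cell types alike. Macrophage markers had a median of 1.69 in wild type and 2.31 in knockout. Fibroblast markers had one of -1.53 and -1.45, smooth muscle markers -1.42 and -2.42, and endothelial markers 0.31 and -3.21. These values do not exclude a lower share together with changes within those cells. Residual blood would raise erythroid markers, which had a median of -0.49 in wild type and 0.13 in knockout. Platelet markers went the other way. In wild type all 7 were higher (median 0.60, camera adjusted p = 0.3), and in knockout the list was higher (camera adjusted p = 0.00126). Erythroid markers alone therefore do not exclude residual blood, which stays open. A larger number of myeloid cells and a change within resident cells also stay open as untested explanations.

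Of 100 groupings of the wild-type arrays, 3, the real one included, passed as many lists as the real one (18, highest other 18). That share is under 0.05, a bound set after the results were seen. Other groupings reached the same count, so chance assignment is not excluded for the lists. In 2 of 10 splits as many lists passed for Max Dep against Min Dep (9, highest other 10), where the splits are too few for a share under 0.05.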

How the results depend on the processing

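The eBayes, robust eBayes, array step, covariate and 6-column settings were chosen after seeing the data, as were the unmoderated wild-type statistics. Among 123 results for named genes, 1885 alternative values gave 1353 with the same direction and side of the threshold, 492 no longer past it, 16 newly past it, 24 that changed sign in genes not past it, and 0 that turned the direction of a called gene. With eBayes, 44 of the 123 results were no longer past the threshold, which was every called one. The same 44 were lost with robust eBayes, and without sham replicate 1 or 2, Min Dep replicate 1 or Max Dep replicate 1. With the control probe set covariate 41 were lost. The gene counts were unstable too, and the cause was not tested unless stated. For CLP against sham (89 genes), array weights gave 294, every probe set 582, an unadjusted p under 0.05 gave 2306, eBayes 0, robust eBayes 0, undoing the array step 179 and the control probe set covariate 1; leaving out 1 array gave 0 to 186. For Max Dep against sham (56), the same settings gave 97, 388, 2071, 0, 0, 47 and 0, with 7 from the 2 groups alone and 0 to 26 with 1 array left out. For Min Dep against sham (7), they gave 6, 118, 2035, 0, 0, 27 and 2, with 1 from the 2 groups alone and 0 to 68 with 1 array left out. For Max Dep against Min Dep (0), an unadjusted p gave 1216, undoing the array step 2, and 1 array left out 0 to 1. For knockout CLP (0), an unadjusted p gave 1476 and all 6 columns 295, and leaving out 1 array gave 0; where that left 1 CLP array, it was assumed to vary like the sham arrays. Fewer arrays leave fewer residual degrees of freedom, which by construction lowers power, yet without Min Dep replicate 2 the counts against sham were 186 for CLP and 68 for Min Dep.

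List counts were 15 to 20 for wild-type CLP (18), 8 to 16 for Max Dep against Min Dep (9) and 21 to 22 for knockout CLP (21) with 1 array left out, and 0 in all 3 with an estimated correlation. The correlation of CLP effects (0.172) was 0.205 with Max Dep alone, 0.109 with Min Dep alone and 0.107 to 0.201 with 1 array left out. Quantile normalisation, median scaling and the 6 septic arrays as 1 group left the wild-type CLP count between 75 and 102. Not run, because the tables hold no levels or folds or differ in unit, were the filter on low values, pseudocounts, the variance trend, the 2-fold threshold, and the tests of a different CLP effect in knockout and wild type with their lists. No paired analysis was possible because the labels give no replicate number shared between groups. Signal over background could not be assessed from these tables.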

Other observations

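No tests were added for these values, and the genes fall under the lists fixed before the data were examined. In knockout hearts 13 of 17 circadian clock genes were lower after CLP (median -0.96 log units, camera adjusted p = 0.00243; adjusted p = 0.418 with an estimated correlation), with Nr1d1 at -4.26 ± 1.06, Cry2 at -3.86 ± 1.01 and Hlf at -3.66 ± 1.21, none past the threshold. In wild-type hearts Nr1d1 differed by -2.07 ± 0.32 standardised units (adjusted p = 0.0543), and the list did not pass (camera adjusted p = 0.197). Fos differed by 4.83 ± 0.71 log units in knockout hearts (adjusted p = 0.0873). Platelet genes Ppbp (3.39 ± 0.46) and Pf4 (2.61 ± 0.41) were higher in septic knockout hearts without passing. Ttr, a carrier protein made mainly in liver, differed by 3.96 ± 0.50 log units in knockout and by 1.34 ± 0.28 standardised units in wild type, whereas Alb differed by 0.51 ± 0.43 and -0.50 ± 0.67.

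Further lists passed camera with the preset and not with an estimated correlation. In wild-type hearts after CLP these were lower genes of cardiac ion channels and junctions (median -0.85), lung epithelium (median -1.08), antigen presentation (median -0.79) and other contractile and energy proteins (median -0.66), and higher cell cycle genes (median 0.43), with adjusted p = 0.241, 0.402, 0.481, 0.241 and 0.479 with an estimated correlation. The lung epithelium genes had a mean of 1.86 in sham replicate 3, against -0.07 and 0.30 in the other sham arrays and -0.80 to 0.06 after CLP, and without that array the list did not pass (camera adjusted p = 0.303). Without sham replicate 2 the antigen presentation, the other contractile and energy and the cell cycle lists did not pass (0.0738, 0.0738 and 0.181), nor did the cell cycle list without sham replicate 3 (0.119) or Max Dep replicate 1 (0.0704). In knockout hearts neutrophil (median 1.25), heat shock (median 1.09), platelet (median 0.90) and ribosomal genes (median 0.69) were higher, and extracellular matrix (median -1.27), sarcomere (median -1.06) and interferon-stimulated genes (median -0.43) lower, with adjusted p = 0.418, 0.530, 0.418, 0.686, 0.615, 0.676 and 0.686 with an estimated correlation. Without knockout CLP replicate 2 the ribosomal and sarcomere lists did not pass (camera adjusted p = 0.184 and 0.482), and without CLP replicate 3 the extracellular matrix and interferon lists did not (0.238 and 0.294). The interferon list also did not pass without sham replicate 1 (0.316), nor the sarcomere list without sham replicate 2 (0.114). Also higher were cytokine (median 0.63), proteasome (median 0.32), antioxidant (median 0.59), fetal and stress response (median 1.19) and cell cycle genes (median 0.40), with adjusted p = 0.530, 0.759, 0.418, 0.522 and 0.454 with an estimated correlation. Without knockout CLP replicate 2 the cytokine and the fetal and stress response lists did not pass (0.125 and 0.482), nor did the proteasome list without CLP replicate 3 (0.218) or sham replicate 1 (0.582).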
